A study of Mus musculus with 18 samples.

How the data were processed

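RNA was measured on 18 single-colour expression arrays that carry Affymetrix control probe sets: mouse embryonic stem (ES) cells, primary embryonic fibroblasts and embryonic brain at E18.5, each with 3 wild-type and 3 cyclin C (Ccnc) knockout samples that the labels call biological replicates. The samples called wild type here are named control in the sample titles. Per the labels' protocols, RNA was extracted with TRIzol and RNeasy columns, and cDNA was primed with oligo-dT and transcribed into biotinylated cRNA, so that signal comes mainly from the 3′ part of transcripts. The log2 expression values were deposited by the authors, who summarised and normalized the probe intensities with RMA (robust multi-array average), per the submitters' processing notes. The RMA version, the array type, the chip definition and whether all 18 arrays were normalized together are not given in the sources used here. RMA makes the overall distribution of the arrays alike, so a change shared by most genes of a cell would not be seen.

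The table held 24185 probe sets, of which 64 were Affymetrix controls and 24121 stood for RefSeq transcripts. Of the transcript probe sets, 22560 matched 1 gene symbol of the RefSeq table (assembly GRCm38.p6) and 1561 matched none; the latter stayed out of the gene tests. A total of 8884 transcript probe sets had exactly the same 18 values as another probe set. For the 3432 genes with more than 1 probe set, the probe set with the highest mean over the 18 arrays stood for the gene, which gave 17091 genes. Among these, 116 genes shared all their values with another gene, in 30 distinct sets of values, and cannot be told apart on these arrays. Values ran from 3.75 to 15.36 and array medians from 8.259 to 8.35 on the log2 scale. No gene was left out for low signal in the tests reported first. Arrays give no read depth, and the 3 arrays per group limit the precision.

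Each cell type was tested alone, knockout against wild type, with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called changed. Effects are log2 fold changes, knockout minus wild type, with the standard error (SE) of the limma fit. A limma model of all 18 arrays with 6 group means gave the mean knockout effect over the 3 cell types and the differences of the effect between cell types. Gene lists, 25 of pathways, complexes and lineages and 13 of cell type or sex markers, were tested with camera from limma, which asks whether the genes of a list moved in one direction relative to all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over all 114 tests. Camera with a correlation estimated from the arrays was run beside it. None of the list calls in the 3 cell types held with the estimated correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

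The comparisons, tests, lists and most alternatives were chosen before the data were examined. So was the rule for named genes: Ccnc; per comparison the 10 genes with the largest increase and the 10 with the largest decrease among called genes whose groups did not overlap and whose higher group mean exceeded the median gene value; up to 4 genes of each list with the smallest p; genes called in the same direction in all 3 cell types, of which there were none; and the 5 genes with the smallest p of the mean effect and of each difference between cell types. With under 5 called genes, the 5 with the smallest p were given as values. This rule names more genes than the text does, and the genes in the text are a subset of them picked after their values were seen. The results of some genes that the rule names are not reported here. The few genes outside the rule are marked where they appear.

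Alternatives planned in advance were 1 fit of all 18 arrays, the replicate number as a block, all probe sets or the mean of a gene's probe sets, a filter at the 40th percentile of gene means, quantile normalization, median centring, eBayes without a trend or with a robust prior, array weights, a 2-fold size threshold, and leaving out each array in turn. Alternatives added after seeing the data were the count of distinct sets of values, fits without the ES cell or fibroblast arrays numbered 1, brain without 6 sex-linked genes, a spread of its own for each cell type, and the other scalings and left-out arrays for the list tests.

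The labels number the replicates 1 to 3 in every group. In fibroblasts, deviations from the group means of same-numbered wild-type and knockout arrays correlated across genes at 0.36, 0.16 and 0.19, and in brain at 0.29, 0.35 and 0.47. The numbers were therefore taken to pair the arrays in these 2 cell types, on the evidence of the values and not of the labels.

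The fits were tested on simulated data with 17091 genes and the real spread of each cell type. At log2 changes of 0.5 and 1, 6% and 78% of changed genes were recovered in ES cells, 92% and 100% in fibroblasts, and 76% and 98% in brain, with 5, 5 and 10 false calls. For the difference between fibroblasts and ES cells 17% and 89% were recovered with 22 false calls, and 5% and 84% with 8 false calls when each cell type had a spread of its own.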

Results

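The series compared gene expression in cyclin C knockout and wild-type mouse cells. Cyclin C is the cyclin partner of the kinases CDK8 and CDK19 and belongs with them to the kinase module of Mediator, the complex that links transcription factors to RNA polymerase II. ES cells, primary embryonic fibroblasts and E18.5 brain were each represented by 3 wild-type and 3 knockout arrays. The spread between replicates differed among the cell types: the median standard deviation (SD) per gene was 0.149 and 0.164 log2 units in wild-type and knockout ES cells, 0.064 and 0.079 in fibroblasts, and 0.117 and 0.105 in brain. Correlations between arrays of 1 group lay between 0.976 and 0.998. The 3′ minus 5′ signal of the Actb and Gapdh control probe sets differed between genotypes by at most 0.07 log2 units in any cell type. The exact permutation p over unpaired arrays was 0.2 or more in each case (2-sided, n = 3 and 3, smallest possible p 0.1). In brain, however, the Gapdh difference was 0.07 higher in the knockout in each of the 3 numbered pairs and the Actb difference was higher by 0.03, 0.01 and 0.02. The exact sign-flip p over 3 pairs was 0.25 for both (2-sided), the smallest that 3 pairs allow.

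Ccnc, the targeted gene, was lower in every knockout array than in every wild-type array of the same cell type. In ES cells it fell from 9.30 ± 0.17 to 6.93 ± 0.35 log2 units (SD, n = 3), a log2 fold change of -2.37 (SE 0.19, limma adjusted p = 0.0247), which left 19.4% of the wild-type signal. In fibroblasts it fell from 9.57 ± 0.03 to 8.27 ± 0.03 (log2 fold change -1.29, SE 0.05, limma adjusted p = 6.77e-06), leaving 40.8%. In brain the means were 8.90 ± 0.30 and 8.21 ± 0.15 (log2 fold change -0.69, SE 0.15, limma adjusted p = 0.627), or 61.8% of wild type. With the paired replicate numbers as a block the adjusted p was 0.0426. A second, dimmer Ccnc probe set gave log2 fold changes of -1.15 in ES cells, -0.76 in fibroblasts and -0.29 in brain (limma adjusted p = 0.487, 0.000789 and 0.642). Relative to ES cells, the reduction was smaller by 1.07 log2 units in fibroblasts (SE 0.22, limma adjusted p of the difference 0.0348) and by 1.67 in brain (SE 0.22, adjusted p = 0.00365). Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so the remaining signal does not measure intact transcript. The ES cell call was lost with the replicate block (adjusted p = 0.0677) or without both arrays numbered 1 (0.0536). It was lost when the mean of both probe sets was tested (log2 fold change -1.76, adjusted p = 0.0733). It was also lost without wild-type array 1, 2 or 3 or knockout array 2 (adjusted p = 0.21, 0.231, 0.11 and 0.299).

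**Figure D1:**
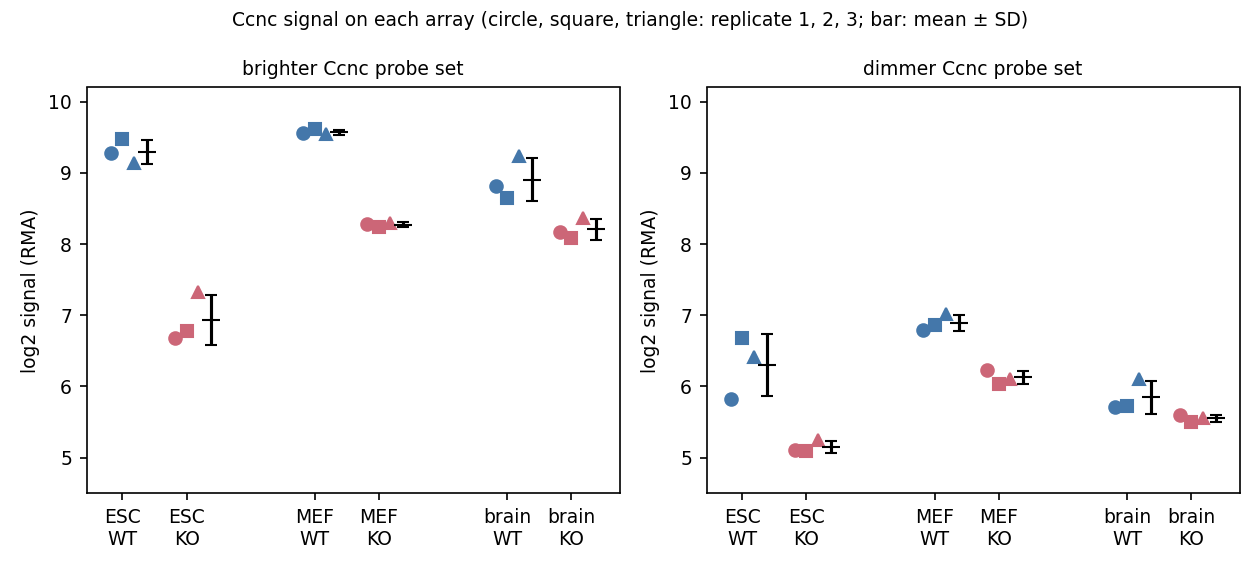
Log2 signal of the brighter and the dimmer Ccnc probe set (vertical axis) on each of the 18 arrays, grouped by cell type and genotype; each point is 1 array and bars are mean ± SD. Knockout arrays lie below wild-type arrays in every cell type, with the widest gap in ES cells (-2.37) and the narrowest in brain (-0.69) for the brighter probe set.

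In knockout fibroblasts, lists of G2/M genes and of G1/S targets of E2F were lower and a list of smooth muscle markers was higher, beside changes of many single genes. Camera gave these 3 lists adjusted p-values of 2.59e-16, 5.77e-09 and 6.66e-05, and adjusted p = 0.651, 0.651 and 0.667 with an estimated correlation. Among genes with signal above the median gene, those that rose most included Ccl2, a chemokine that attracts monocytes (log2 fold change 1.44, SE 0.08), Krt18, a keratin of simple epithelia (1.38, SE 0.11), and Tgm2, which encodes transglutaminase 2 (1.36, SE 0.10). The interferon-inducible chemokine Cxcl10 (1.02, SE 0.10) and the adhesion molecule gene Icam1 (0.87, SE 0.07) rose as well. Uchl1 (0.85), Sbsn (0.80), Glipr1 (0.78) and Nppb, which encodes B-type natriuretic peptide (0.78), also rose. Among the genes that fell were C1qtnf3 (-1.58, SE 0.28), the complement regulator Cd55 (-1.53, SE 0.08), Ifi204 (-1.44, SE 0.28), the cyclin E2 gene Ccne2 (-1.28, SE 0.11) and the histone H3 gene H3c15 (-1.26, SE 0.20). Others were Dcn, which encodes the matrix proteoglycan decorin (-1.22, SE 0.10), Gap43 (-1.20, SE 0.11), the tachykinin gene Tac1 (-1.16, SE 0.07) and Matn2 (-1.15, SE 0.07). The angiotensin receptor gene Agtr2 (-1.94, SE 0.16) and the chemokine gene Cxcl3 (-1.90, SE 0.17), dimmer than the median gene, fell further. Adjusted p-values of these genes ran from 4.04e-05 for Ccl2 and Cd55 to 0.0106 for Ifi204 (limma), and each had the 3 knockout arrays on 1 side of the 3 wild-type arrays. In all, 2058 of 17091 genes changed, 1216 up and 842 down, against 4540 genes with an unadjusted p below 0.05 where 855 would be expected by chance. The groups did not overlap for 30.9% of genes, against 10% by chance. Most changes were small, with a median absolute log2 fold change of 0.30, and 30 genes changed at least 2-fold, 7 up and 23 down. With quantile normalization the split was 1042 up and 1076 down, and with 1 fit of all 18 arrays 210 genes were called. Without wild-type array 1, 2 or 3 or knockout array 2 the count was 1306, 1088, 1104 and 900. Of 78 named fibroblast genes, 57 kept the call without each array in turn and 45 lost it in 1 fit of all 18 arrays, such as Icam1 (adjusted p = 0.119) and Pdgfra (0.192). That fit gives fibroblasts a spread shared with ES cells and brain, whose replicates varied more, so it can overstate the spread of fibroblasts. C1qtnf3 and Ifi204 were not called with a robust prior (adjusted p = 0.0732 and 0.0665).

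**Figure D2:**
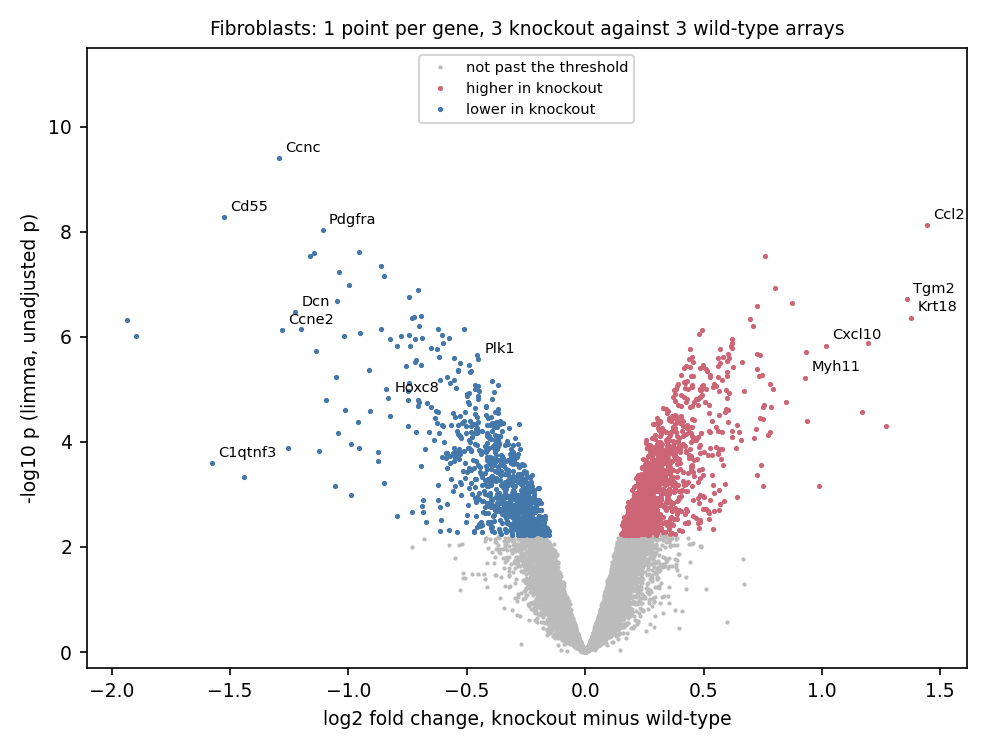
Log2 fold change, knockout minus wild type (horizontal axis), against -log10 of the unadjusted limma p (vertical axis) for the 17091 genes in fibroblasts. Each point is 1 gene, and colours mark the 1216 genes called higher and the 842 called lower. Ccl2, Krt18 and Tgm2 lie at 1.44, 1.38 and 1.36, and C1qtnf3 and Cd55 at -1.58 and -1.53.

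Of 21 measured G2/M genes, 17 fell, 0 rose and 4 were not called in knockout fibroblasts (20 fell when adjusted over the list alone). Among them were the spindle midzone gene Prc1 (log2 fold change -0.46, SE 0.05), the mitotic kinase genes Plk1 (-0.45, SE 0.05) and Aurka (-0.38, SE 0.05), and Nusap1 (-0.47, SE 0.06). Of 26 measured G1/S targets of E2F, 11 fell, 0 rose and 15 were not called (14 fell when adjusted over the list alone). These included the E2F-binding pocket protein gene Rbl1 (-0.54, SE 0.06), the ribonucleotide reductase gene Rrm1 (-0.40, SE 0.05) and the cyclin A2 gene Ccna2 (-0.41, SE 0.06). Camera called both lists, and neither call held with an estimated correlation (adjusted p = 0.651 for each). Under quantile normalization 20 G2/M genes and 13 G1/S genes fell. Smooth muscle markers had a median log2 fold change of 0.37 and fibroblast markers of -0.02 in the same arrays.

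Smooth muscle markers and the keratin genes Krt18, Krt8 and Krt19 rose in knockout fibroblasts. Of 10 smooth muscle and myofibroblast markers, 6 rose and 0 fell (8 rose when adjusted over the list alone). They included smooth muscle myosin, Myh11 (log2 fold change 0.93, SE 0.10), calponin, Cnn1 (0.48, SE 0.09), Myl9 (0.49, SE 0.10) and tropomyosin 1, Tpm1 (0.26, SE 0.04). Camera gave an adjusted p = 6.66e-05, and 0.667 as the adjusted p with an estimated correlation. Of 9 epithelial markers, the keratin genes Krt18, Krt8 (0.93, SE 0.09) and Krt19 (0.56, SE 0.09) rose and 0 fell, and 4 rose when adjusted over the list alone. The epithelial list passed camera with the replicate block (adjusted p = 0.0358) and with quantile normalization (0.0374), against 0.0566 without either. Its adjusted p with an estimated correlation was 0.667. Of 15 targets of TGF-β, 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0424, and adjusted p = 0.667 with an estimated correlation). Ltbp2 (0.51, SE 0.06) and Bhlhe40 (0.45, SE 0.07) were among those that rose. Markers of fibroblasts themselves moved both ways. Of 18, 5 rose, such as the collagen gene Col6a3 (0.48, SE 0.05) and the collagen cross-linking enzyme gene Lox (0.37, SE 0.05), and 7 fell, such as Dcn and the PDGF receptor gene Pdgfra (-1.11, SE 0.06). Adjusted over the list alone 6 rose and 7 fell, under quantile normalization 3 rose and 7 fell, and camera gave no call (adjusted p = 0.28). Cnn1 and Myl9 were not called without knockout array 2 (adjusted p = 0.0556 and 0.0774). The TGF-β list was not called without wild-type array 3, knockout array 1 or knockout array 3 (adjusted p up to 0.214) or with quantile normalization (0.0521).

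Of 20 inflammatory and secretory senescence genes, 8 rose, 1 fell and 11 were not called in knockout fibroblasts (8 rose and 3 fell adjusted over the list alone). Those that rose included the chemokine genes Ccl2 and Ccl7 (0.72, SE 0.06), Csf1, the macrophage growth factor gene (0.62, SE 0.06), and the cytokine gene Lif (0.41, SE 0.08). Camera gave an adjusted p = 0.0296 for this list, and the adjusted p was 0.667 with an estimated correlation and 0.102 without wild-type array 3. Interferon-stimulated genes moved both ways, 4 up and 3 down of 25 (9 and 4 adjusted over the list alone; camera adjusted p = 0.712). Ifit2 (0.40, SE 0.09) and Gbp2 (0.52, SE 0.13) rose, while the transcription factor gene Irf7 (-0.69, SE 0.15) and the peptide transporter gene Tap1 (-0.53, SE 0.09) fell. With quantile normalization the same list held 2 genes up and 3 down. Ifit2, Gbp2 and Irf7 each lost the call when single arrays were left out. These were wild-type array 1 or 2 for all 3 genes, wild-type array 3 for Irf7, knockout array 2 for Ifit2 and knockout array 3 for Gbp2 (adjusted p up to 0.0925, for Gbp2).

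Other regulators changed in fibroblasts as well. Of 31 Hox genes, which pattern the body axis, 5 fell and 0 rose, the same numbers as when adjusted over the list alone. They included Hoxa10 (-0.85, SE 0.17), Hoxc8 (-0.83, SE 0.10), Hoxc10 (-0.72, SE 0.07) and Hoxc6 (-0.38, SE 0.06). Camera gave an adjusted p = 0.00595, and an adjusted p = 0.519 with an estimated correlation. Among 23 serum response genes 10 rose and 5 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.122). Klf2 (-1.05, SE 0.08) and Klf4 (-0.46, SE 0.07) fell, and Ier3 (0.38, SE 0.05) and Ccn1 (0.36, SE 0.06) rose. Of 18 genes of the ATF4 stress response 4 fell and 0 rose (7 fell and 1 rose adjusted over the list alone), including Atf5 (-0.30, SE 0.05) and Trib3 (-0.42, SE 0.10). Camera gave an adjusted p = 0.0424 for the ATF4 list, and an adjusted p = 0.738 with an estimated correlation. Of 16 NRF2 targets 5 rose and 0 fell (6 adjusted over the list alone; camera adjusted p = 0.093). Among them were the heme oxygenase gene Hmox1 (0.76, SE 0.10), Txnrd1 (0.29, SE 0.05), Gclc (0.37, SE 0.07) and Gsta4 (0.28, SE 0.06). Trib3 lost the call without any of wild-type arrays 1 and 2 and knockout arrays 2 and 3 (adjusted p up to 0.0948), as did the ATF4 list (up to 0.139). Gclc lost it without knockout array 2 (0.0545), and Gsta4 without wild-type array 1 or knockout array 2 (0.0614 and 0.0778).

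Within Mediator itself, Cdk8, the kinase that cyclin C binds, rose slightly in knockout fibroblasts (log2 fold change 0.37, SE 0.04, limma adjusted p = 0.00121), and 5 of the 7 kinase module genes did not pass the test. Of 25 core Mediator genes 4 rose and 0 fell, Med15 (0.23, SE 0.05), Med31 (0.25, SE 0.05), Med14 (0.25, SE 0.05) and Med25 (0.22, SE 0.05). Adjusted over the list alone 6 rose and 1 fell, and under quantile normalization over all genes 5 rose and 1 fell. Of 15 Notch target genes 3 rose and 0 fell (5 adjusted over the list alone): Notch1 (0.25, SE 0.05), Myc (0.31, SE 0.07) and Notch3 (0.39, SE 0.09). Of 20 Notch pathway components 3 rose and 1 fell, also when adjusted over the list alone, with the ligand gene Jag1 (0.57, SE 0.13) up and the sheddase gene Adam10 (-0.28, SE 0.05) down. Camera made no call for these 4 lists (adjusted p = 0.252 for the kinase module, 0.627 for core Mediator, 0.093 for Notch targets and 0.248 for Notch components). Med14, Med15, Med25, Med31, Myc, Notch3 and Jag1 each lost the call without knockout array 2 (adjusted p from 0.0579 for Med15 to 0.113 for Med25). Calls were also lost without wild-type array 1 (Med31, Myc, Notch3) or wild-type array 2 (Med14, Med25, Med31, Notch3). They were lost as well without wild-type array 3 (Med14, Med15, Med25, Myc, Notch3) or knockout array 3 (Med25, Notch3), with adjusted p up to 0.0994.

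**Figure D3:**
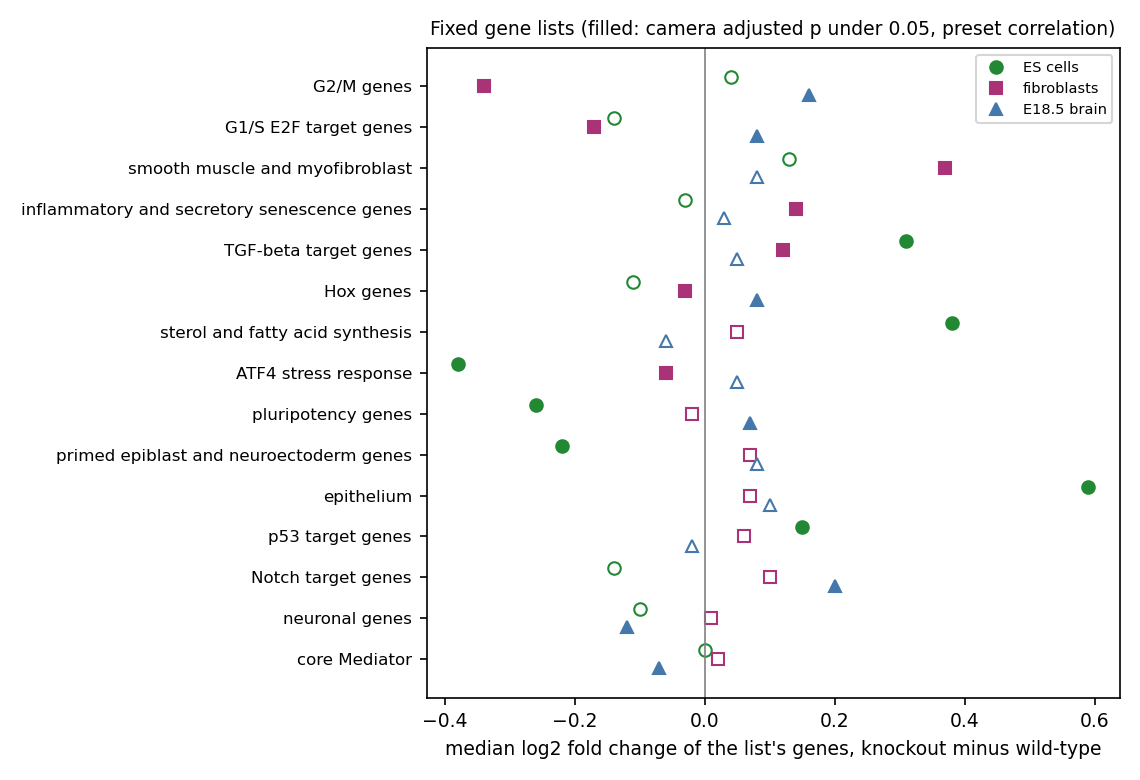
Median log2 fold change, knockout minus wild type (horizontal axis), of the measured genes of gene lists that camera called in at least 1 cell type (the mesendoderm and interneuron lists, also called, are not drawn). Symbols separate ES cells, fibroblasts and brain, and filled points passed camera with the preset correlation. The G2/M list lies at -0.34 in fibroblasts and at 0.16 in brain, and the sterol list at 0.38 in ES cells.

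In knockout ES cells, camera with the preset correlation called a list of lipid synthesis genes higher and lists of stress response and pluripotency genes lower, with no member called over all genes and no list call kept with an estimated correlation. All 22 measured genes of sterol and fatty acid synthesis had a higher knockout mean, with a median log2 fold change of 0.38, and 8 rose when adjusted over the list alone, against 0 over all genes. Values included the stearoyl-CoA desaturase genes Scd1 (1.14, SE 0.12, limma adjusted p = 0.0738) and Scd2 (0.82, SE 0.10), Sc5d of cholesterol synthesis (0.97, SE 0.14) and the squalene epoxidase gene Sqle (0.50, SE 0.11). Of 18 ATF4 stress response genes 17 had a lower knockout mean, such as Chac1 (-1.18, SE 0.34), Trib3 (-0.64, SE 0.18), Ddit3 (-0.58, SE 0.17) and Herpud1 (-0.34, SE 0.12). Of 24 pluripotency genes 22 had a lower knockout mean, with values of -0.74 for Klf2 (SE 0.21), -0.50 for Tdgf1 (SE 0.23), -0.39 for Fbxo15 (SE 0.20) and -0.38 for Tet2 (SE 0.16). No gene of the last 2 lists passed when adjusted over the list alone or over all genes. In the same arrays, 10 endoderm genes chosen after their values were seen had a mean of 11.88 in knockout array 1, against 8.47 and 8.75 in knockout arrays 2 and 3 and 9, 7.98 and 8.03 in the wild-type arrays. Camera gave adjusted p-values of 5.43e-14, 3.28e-06 and 0.00187 for these 3 lists, and adjusted p = 0.519, 0.667 and 0.667 with an estimated correlation. The pluripotency list was not called without wild-type array 2 or knockout array 1 (adjusted p up to 0.0891). Without both arrays numbered 1 all 3 lists kept their direction and call. Their camera adjusted p with the preset correlation was then 1.76e-11 for sterol, 0.00384 for ATF4 and 0.00181 for pluripotency genes.

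Camera with the preset correlation called 5 further lists in ES cells, with no member called over all genes. Epithelial markers were higher in 8 of 9 cases, with values of 1.62 for the claudin gene Cldn6 (SE 0.61), 1.11 for Cldn7 (SE 0.33) and 0.36 for the E-cadherin gene Cdh1 (SE 0.09). Of them, 1 rose when adjusted over the list alone (camera adjusted p = 0.00128, and adjusted p = 0.667 with an estimated correlation, which was 0.653 between these genes). In the same arrays the 10 endoderm genes had a mean of 11.88 in knockout array 1 against 8.47 and 8.75 in the other knockout arrays, and without both arrays numbered 1 the epithelial list had an adjusted p of 0.000105. TGF-β targets were higher in 10 of 15 cases, with Id2 at 1.67 (SE 0.33). Again 1 rose when adjusted over the list alone (adjusted p = 0.00921, and 0.556 as the adjusted p with an estimated correlation). Targets of p53 were higher in 15 of 22 cases, with Perp at 0.71 (SE 0.24), Btg2 at 0.55 (SE 0.18) and Phlda3 at 0.43 (SE 0.13; adjusted p = 0.0144, and adjusted p = 0.651 with an estimated correlation). Primed epiblast and neuroectoderm genes were lower in 11 of 13 cases, with Zic2 at -0.88 (SE 0.25) and Pou3f1 at -0.69 (SE 0.21; adjusted p = 0.0094, and adjusted p = 0.651 with an estimated correlation). Interneuron genes were lower in 10 of 12 cases (adjusted p = 0.0424, and adjusted p = 0.651 with an estimated correlation). For p53 targets, primed epiblast genes and interneuron genes, 0 passed when adjusted over the list alone. The primed epiblast list was not called without both arrays numbered 1 (adjusted p = 0.198) or without wild-type array 1 (0.109). The p53 list was not called without wild-type array 1 or knockout array 3 (up to 0.16) or with quantile normalization (0.0855), nor the interneuron list with quantile normalization (0.192) or without any array other than knockout array 1 (up to 0.104).

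Only 2 genes were called in ES cells: 4933402E13Rik, a gene known here by its clone name, rose (log2 fold change 3.33, SE 0.23, limma adjusted p = 0.0161), and Ccnc fell. The next genes by p, given as values, were Gng10 (1.10, SE 0.11), Scd1 and Fthl17a (1.59, SE 0.17), all at an adjusted p of 0.0738, and the immediate early gene Egr1 stood at -2.14 (SE 0.32, adjusted p = 0.295). With an unadjusted p below 0.05 there were 1446 genes, against 855 expected by chance, and the groups did not overlap for 15.6% of genes, against 10% by chance. Knockout array 1 stood apart from the other knockout arrays in 10 genes of endoderm, by 2.07 log2 units for Sox7 to 5.03 for Cubn, with Gata4 at 2.82, Gata6 at 3.12 and Sox17 at 2.77. These 10 genes were chosen after their values were seen. Wild-type array 1 exceeded the other wild-type arrays by a median of 0.80 in the same genes. Both arrays numbered 1 had higher signal of the Y-linked gene Eif2s3y (8.24 and 7.46) than the other 4 ES cell arrays (4 to 4.27). Their mean of 4 X-linked genes that escape inactivation was lower (10.61 and 10.45, against 11.17 to 11.51). The count was 0 without wild-type array 1, 2 or 3 or knockout array 2, 6 without knockout array 1, and 6 without both arrays numbered 1. It was 5 after the filter on dim genes, 4 with array weights, 1 with the mean of a gene's probe sets and 632 with 1 fit of all 18 arrays. With the fit of all arrays Scd1, Scd2, Sc5d, Sqle, Egr1, Gng10 and Fthl17a passed the threshold too. That fit shares 1 spread, although the median SD was 0.149 and 0.164 in ES cells and 0.064 and 0.079 in fibroblasts. It can thus understate the spread of ES cells, and these passes are not separate support.

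**Figure D4:**
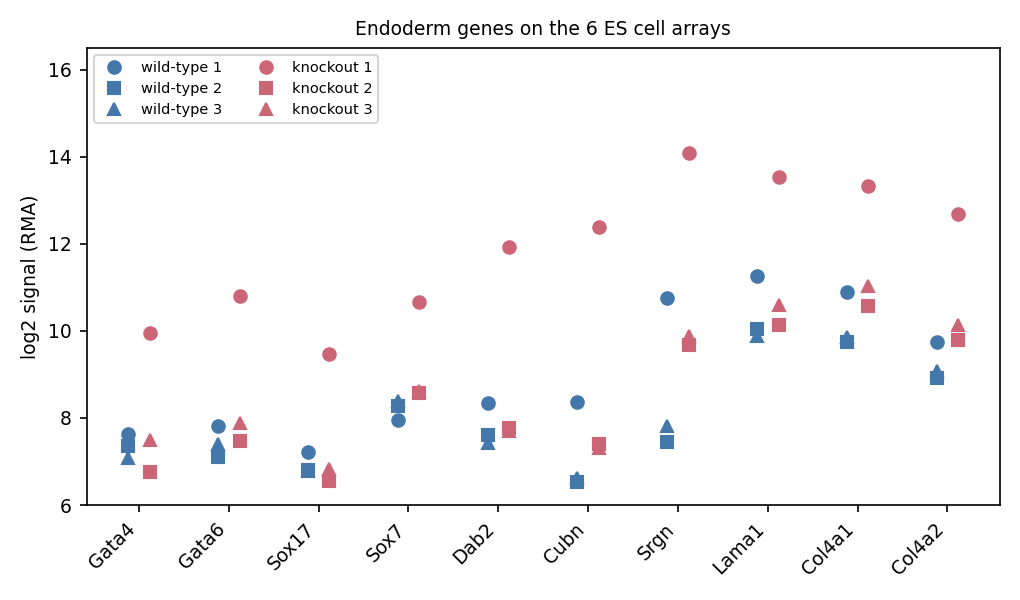
Log2 signal (vertical axis) of 10 endoderm genes on the 6 ES cell arrays; each point is 1 gene on 1 array. Knockout array 1 lies above the other arrays in every gene, and wild-type array 1 lies above the other wild-type arrays in all but Sox7.

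In brain, single genes moved little apart from genes on the sex chromosomes. Xist, the X-inactivation RNA expressed in female cells, fell by 3.69 log2 units (SE 0.15, limma adjusted p = 4.81e-05) and was the only gene called. Wild-type arrays had Xist between 12.25 and 12.40 and knockout arrays between 8.29 and 8.96. The Y-linked genes Eif2s3y (1.05, SE 0.13), Ddx3y (0.83, SE 0.18) and Kdm5d (0.65, SE 0.13) had higher knockout values, and 4 sex-linked genes rose and 1 fell when adjusted over the list of 6 alone. The brain gene groups described here were measured on these same arrays. The next genes by p were the protocadherin gene Pcdh8 (0.73, SE 0.10), Eda2r (0.59, SE 0.09) and Nxph2 (-0.49, SE 0.08), with adjusted p of 0.376, 0.376 and 0.456. With an unadjusted p below 0.05 there were 1252 genes, against 855 expected, and 14% of genes did not overlap between the groups, against 10% by chance. With the replicate block 15 genes were called, 4 up and 11 down. Among them were Xist, Eif2s3y, Pcdh8, the intermediate filament gene Vim (0.55), the somatostatin gene Sst (-0.69), Ccnc and, named after its values were seen, Fgfbp3 (1.15, adjusted p = 0.000355). The count was 2 without wild-type array 3, where Ddx3y joined (1.06, adjusted p = 0.0488), and 2 over all probe sets. It was 0 without the 6 sex-linked genes or with 1 fit of all 18 arrays, where Xist had an adjusted p of 0.265.

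**Figure D5:**
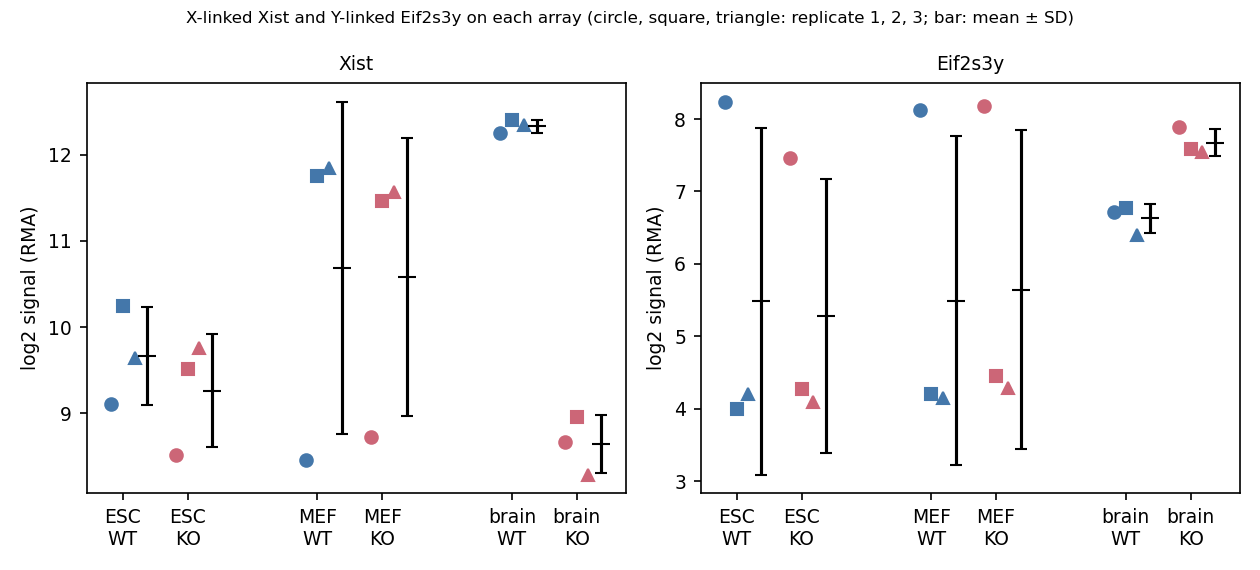
Log2 signal (vertical axis) of Xist and of the Y-linked gene Eif2s3y on each of the 18 arrays, grouped by cell type and genotype; each point is 1 array and bars are mean ± SD. In brain, Xist is at 12.25 to 12.40 in wild-type and 8.29 to 8.96 in knockout arrays, while in ES cells and fibroblasts the arrays numbered 1 of both genotypes carry the Eif2s3y signal.

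In knockout brain, lists of Notch targets, G2/M genes and G1/S targets were higher and a list of neuronal genes was lower by camera, with no member called over all genes. Of 15 Notch target genes 12 had a higher knockout mean, such as Hes1 (0.30, SE 0.09), Hey2 (0.28, SE 0.11) and Notch3 (0.29, SE 0.13; camera adjusted p = 0.00128, and adjusted p = 0.519 with an estimated correlation). Of 21 G2/M genes 18 were higher, such as Ccnb1 (0.50, SE 0.17), Tpx2 (0.43, SE 0.14), Ccnb2 (0.37, SE 0.14) and Prc1 (0.30, SE 0.12; adjusted p = 0.000289, and 0.667 as the adjusted p with an estimated correlation). Likewise 22 of 26 G1/S targets of E2F were higher (adjusted p = 0.0358, and adjusted p = 0.728 with an estimated correlation). Of 20 neuronal genes 17 were lower, such as the cortical transcription factor gene Tbr1 (-0.39, SE 0.18), the glutamate transporter gene Slc17a7 (-0.30, SE 0.13) and Map2 (-0.26, SE 0.09). Of these 1 fell when adjusted over the list alone (adjusted p = 0.00465, and adjusted p = 0.519 with an estimated correlation). Interneuron genes were lower in 9 of 12 cases, with Sst at -0.69 (SE 0.14), Calb2 at -0.49 (SE 0.23) and Lhx6 at -0.42 (SE 0.21). There 1 fell when adjusted over the list alone, but camera gave no call (adjusted p = 0.0813). The neural progenitor list, with Vim at 0.55 (SE 0.12), had 1 gene that rose when adjusted over the list alone. It passed with the replicate block (adjusted p = 0.0364) or quantile normalization (0.041) and not without them (0.117; adjusted p = 0.667 with an estimated correlation). These shifts stood beside the Xist and Y-linked differences above and a 3′ minus 5′ signal of Gapdh that was 0.07 higher in the knockout array of each numbered pair. The G2/M list was not called without knockout array 1 (adjusted p = 0.203), the G1/S list without wild-type array 2 or knockout array 1 (up to 0.721), and the neuronal list with quantile normalization (0.121).

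Further list calls in brain, on the same arrays with a higher 3′ minus 5′ signal of Gapdh in the knockout (0.07 in each pair), covered core Mediator genes, lower in 21 of 25 cases (camera adjusted p = 0.0144). Hox genes were higher in 22 of 31 cases with Hoxc8 at 0.81 (SE 0.18) and Hoxb8 at 0.51 (SE 0.21; adjusted p = 0.0272). Pluripotency genes were higher in 15 of 24 cases with the neural stem cell gene Sox2 at 0.36 (SE 0.13), and mesendoderm genes in 17 of 20 cases (adjusted p = 0.0429 for each). The adjusted p with an estimated correlation was 0.667 for all 4 lists, and 0 genes passed when adjusted over each list alone. None of the 4 lists was called with quantile normalization (adjusted p = 0.121, 0.105, 0.121 and 0.154, in the order given). Calls were lost without wild-type array 1 or knockout array 2 for core Mediator (adjusted p up to 0.132) and without wild-type array 3 or knockout array 1 for Hox genes (up to 0.999). Without wild-type array 1 or 3 or knockout array 2 they were lost for pluripotency genes (up to 0.234) and mesendoderm genes (up to 0.349).

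The mean effect over the 3 cell types was called for 51 genes, 33 up and 18 down. Those with the smallest p were Ccnc (-1.45, SE 0.09), 4933402E13Rik (1.15, SE 0.09), Agtr2 (-0.76, SE 0.09), the prostaglandin E synthase gene Ptges (0.39, SE 0.05) and Gap43 (-0.71, SE 0.09). A called mean does not show an effect in each cell type. In ES cells, fibroblasts and brain 4933402E13Rik stood at 3.33, 0.08 and 0.05, and Agtr2 at -0.13, -1.94 and -0.21. Of the 51, 40 had the same sign in all 3 cell types, 26 up and 14 down, which selection by the mean effect itself favours, so that this count is not evidence of shared effects. Over all genes, without that selection, 23.6% had the same sign in all 3, against 25% by chance. Across genes, which are not independent replicates, log2 fold changes correlated between ES cells and fibroblasts at Pearson's r of 0.091 (Spearman's rho 0.094), between ES cells and brain at 0.005 (-0.029) and between fibroblasts and brain at -0.092 (-0.113). Ccnc, the gene deleted by design, was the only gene called in both ES cells and fibroblasts (0 with the mean of a gene's probe sets), and no gene was shared with brain. Only 6% of simulated changes of 0.5 log2 units were recovered in ES cells, so that few shared calls do not show that the effects differed. Of the 1216 genes higher in knockout fibroblasts, 64% were also higher in knockout ES cells, against 42.7% of all genes, and 38.3% were higher in knockout brain, against 50.5% of all genes. Of the 842 genes lower in knockout fibroblasts, 54.4% were lower in ES cells and 44.1% in brain, against 57.3% and 49.5% of all genes.

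The effect differed between fibroblasts and ES cells for 170 genes, 76 higher and 94 lower in fibroblasts, between brain and ES cells for 47, and between fibroblasts and brain for 57. The class I histocompatibility gene H2-D1 fell in fibroblasts (-1.05) and stood at 0.93 in ES cells (difference -1.98, SE 0.24, limma adjusted p = 0.00138). Agtr2 stood at -1.94, -0.13 and -0.21 in fibroblasts, ES cells and brain (difference from ES cells -1.81, adjusted p = 0.00138). Ccl2 had a log2 fold change higher in fibroblasts than in brain by 1.55 (SE 0.195, adjusted p = 0.00356), and Hoxc8 lower by 1.64 (SE 0.23, adjusted p = 0.0081). These fits share 1 spread between cell types of unequal spread. With a spread of its own for each cell type the mean effect counted 89 genes and the 3 differences 53, 3 and 539. Without both ES cell arrays numbered 1 they were 402, 553, 474 and 226. The replicate block and array weights moved these counts too, as given in the section on processing below. Leaving out single arrays moved the mean effect to 193, 83, 155 and 204 genes (ES wild-type arrays 1 and 3, ES knockout arrays 1 and 2). It moved it to 28, 26, 25 and 21 (fibroblast wild-type arrays 1 to 3, knockout array 2) and to 32, 33 and 32 (brain wild-type array 1, knockout arrays 2 and 3). It moved the difference between fibroblasts and ES cells to 30 to 73 genes without any 1 fibroblast array and to 282, 376 and 391 without ES wild-type array 1 and knockout arrays 1 and 2. The difference between brain and ES cells went to 19 or 20 genes without any 1 fibroblast array, to 9 to 30 without any 1 brain array. It went to 158, 86, 209 and 220 without ES wild-type arrays 1 and 3 and knockout arrays 1 and 2. The difference between fibroblasts and brain went to 19, 6, 14, 6 and 17 without fibroblast wild-type arrays 1 to 3 and knockout arrays 2 and 3. It went to 8, 28, 14 and 37 without brain wild-type arrays 1 and 2 and knockout arrays 1 and 3, and to 115 without ES knockout array 1.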

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

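The explanations for Xist in brain, endoderm genes in ES cells and cell cycle genes in fibroblasts, the 114 tests of gene lists between cell types, and the counts over splits of all 18 arrays that part the pairs or keep the real fibroblast groups were tested only after the results were seen; the counts over other splits were planned.

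Xist fell by 3.69 log2 units in knockout brain. A loss of Xist between brains of 1 sex was argued against, since the mean of 4 Y-linked genes was 0.71 log2 units higher in knockout brain (SD 0.14 in wild type and 0.16 in knockout). Mixed-sex wild-type brain against male knockout brain may account for the lower Xist: the mean of the measured X-linked genes that escape inactivation differed by -0.20 (SD 0.09 and 0.04). Wholly female wild-type brain was argued against by the Y-linked genes. Their mean was 7.08, 7.13 and 7.34 in the wild-type brain arrays. In the ES cell and fibroblast arrays numbered 2 and 3 it was 5.01 to 5.37. The labels used here give no sex, and the sex-linked signals went with the genotype in these 6 arrays, so that sex and genotype both stayed open for the other brain differences.

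Endoderm genes stood apart in ES cell knockout array 1, with a median rise of 2.97 log2 units over the other knockout arrays. RNA of feeder fibroblasts was argued against, since 10 of the 10 genes were lower in wild-type fibroblasts than in that array. These genes were picked for standing high there, and not all of the 14 further endoderm genes below were lower in fibroblasts. Fibroblast genes, 6 in number and not so picked, rose by a median of 0.25 in that array. Their median against wild-type fibroblasts was -6.03, which argues against feeder RNA too. A knockout effect alike in all cultures would not by itself set 1 array apart. In that array the mean of 14 further endoderm genes exceeded the higher of knockout arrays 2 and 3 by 1.52, while these differed by 0.17. The array was singled out for standing apart in endoderm genes, so that this value extends the pattern to more genes and is not a separate test of the cause. A smaller effect in all cultures stayed open, since the 10 genes had a median of 0.21 in knockout arrays 2 and 3 over wild type, just above the bound of 0.2 first set for arguing against it, and of 0.80 in wild-type array 1 over the other wild-type arrays. Endoderm-like cells in that culture are a candidate explanation, since the 14 further genes had a median rise of 1.32 and 12 of them were higher.

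Of 21 G2/M genes 17 fell in knockout fibroblasts, and of 26 G1/S targets 11, while both list calls were lost with an estimated correlation (adjusted p = 0.651 for each). A further quantile normalization of the fibroblast arrays left 20 of the G2/M genes lower, which argues against remaining scale differences between these arrays. The authors' normalization itself stayed open, since RMA had already made the distributions of the deposited values alike. A lower share of fibroblasts stayed open: 0 marker lists of other cell types had a mean below 0 by over 2 standard errors. Smooth muscle, endothelium and macrophage lists lay above 0 by more than that. These standard errors were taken over the genes of a list, which are not independent replicates. Camera called the smooth muscle list (adjusted p = 6.66e-05, and 0.667 with an estimated correlation). It did not call the endothelium (0.0648) or the macrophage list (0.486). A different growth state of the cultures at harvest might also account for a median of -0.34, and each culture had 1 genotype, so that no value here decides between growth state and knockout.

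The knockout effect differed between fibroblasts and ES cells for 170 genes, between brain and ES cells for 47 and between fibroblasts and brain for 57, by a limma test of the difference itself. Camera over all 38 lists and 3 pairs of cell types, 114 tests, called 18 differences with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.199). In fibroblasts against brain the median differences were -0.48 for G2/M genes (lower in 21 of 21 cases, adjusted p = 4.11e-19), -0.28 for G1/S targets of E2F, -0.16 for Hox genes and -0.14 for ATF4 genes. In fibroblasts against ES cells they were -0.34 for G2/M genes (adjusted p = 3e-10), -0.27 for sterol and fatty acid synthesis (3e-10), 0.22 for Notch targets, 0.27 for ATF4 genes and 0.32 for primed epiblast genes. In brain against ES cells they were -0.37 for sterol and fatty acid synthesis (adjusted p = 2.26e-13), 0.43 for ATF4 genes (3.57e-07), 0.34 for Notch targets, 0.31 for primed epiblast genes, 0.27 for Wnt targets, 0.26 for pluripotency genes, 0.24 for adipocyte markers, 0.20 for Hox genes and 0.17 for G1/S targets. The adjusted p-values of the 18 differences with the preset correlation reached 0.0409.

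Named genes with a lower effect in fibroblasts than in ES cells were 4933402E13Rik (difference of log2 fold changes -3.25), H2-D1 (-1.98), Cd55 (-1.84), Agtr2 (-1.81), Cxcl3 (-1.76), C1qtnf3 (-1.65), Fthl17a (-1.54), Rspo2 (-1.47), Ifi204 (-1.43), Matn2 (-1.41), Gng10 (-1.23), Dok2 (-1.16), Scd1 (-1.08), Sc5d (-1.06), Hoxc10 (-1.03), Nabp1 (-0.95), Scd2 (-0.79), Prc1 (-0.65), Aurka (-0.63), Ccna2 (-0.57) and Sqle (-0.53). Those with a higher effect in fibroblasts were Egr1 (1.82), Ubd (1.65), Uchl1 (1.30), Ccl2 (1.26), Myh11 (1.08), Ccnc (1.07), Ccl7 (0.89), Col6a3 (0.84), Csf1 (0.68), Gclc (0.68) and Nes (0.66). Between brain and ES cells the effect was lower in brain for 4933402E13Rik (-3.28), Id2 (-2.06), Fthl17a (-1.70), Dok2 (-1.24), Scd1 (-1.17), Sc5d (-0.99), Scd2 (-0.91) and Sqle (-0.58), and higher for Egr1 (1.91), Ubd (1.71) and Ccnc (1.67). Between fibroblasts and brain it was lower in fibroblasts for Cxcl3 (-1.83), Agtr2 (-1.72), Hoxc8 (-1.64), C1qtnf3 (-1.63), Cd55 (-1.59), Klf2 (-1.24), Matn2 (-1.22), Rspo2 (-1.15), Nabp1 (-1.10), Hoxc10 (-0.83) and Prc1 (-0.76), and higher for Ccl2 (1.55). Of 1561 probe sets with no gene name, which entered no gene test, 81 passed the threshold in fibroblasts, 47 up and 34 down, and 0 in ES cells and in brain.

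The 10 splits of the 6 arrays of a cell type are too few for a share under 0.05. The real split called 2058 genes in fibroblasts, more than any other (highest other 0), so that 1 of 10 splits gave as many. In ES cells it called 2 (highest other 2), and 2 of 10 splits gave as many. In brain it called 1 (highest other 1), and 2 of 10 gave as many. Among the splits that parted all numbered pairs, the highest other count was 0 in fibroblasts and in brain. Of 100 drawn splits of all 18 arrays within the cell types, 1 gave as many genes as the real one for the mean effect (51, highest other 10), 1 for fibroblasts against ES cells (170, highest other 56), 3 for brain against ES cells (47, highest other 127) and 1 for fibroblasts against brain (57, highest other 18). These splits ignored the pairs. Of 100 drawn splits that parted all numbered pairs of fibroblasts and brain, as the real one does, 1, 4, 1 and 1 gave as many genes for these 4 counts (highest other 39, 412, 32 and 54). Each share was under 0.05 in both draws. The shares of 3 and 4 of 100, for brain and for fibroblasts against ES cells, lie too near 0.05 for 100 draws to exclude chance. For the mean effect and fibroblasts against brain, 1 of 100 in both draws argued against chance over regroupings of all arrays. The draws leave open whether the effect of 1 cell type alone gives the count. For fibroblasts against ES cells the splits do not exclude that the fibroblast effect alone gives it: of 28 splits that kept the real fibroblast groups, the real one included, 4 gave as many genes (14.3%), and the rest of the 100 gave 10 at most. In the same 28 splits the highest other count was 54 for fibroblasts against brain (real 57) and 39 for the mean effect (real 51). The rest gave 0 and 5 at most. Other splits thus came near these 2 counts only where the real fibroblast groups were kept. The splits above the real count for brain against ES cells, with 120 and 127 genes, shared 1 grouping of the ES cell arrays and 1 of the brain arrays. Those above it for fibroblasts against ES cells, with 261, 327 and 412 genes, kept the real fibroblast groups and had both ES cell arrays numbered 1 on 1 side. The splits with 120 and 127 genes also had these arrays on 1 side, while the real split parts them. Both had a higher mean of 4 Y-linked genes (7.22 and 6.64) than the other ES cell arrays (5.01 to 5.13). Their mean of X-linked genes that escape inactivation was lower (10.61 and 10.45, against 11.17 to 11.51). Such splits thus held a sex-linked contrast that the real split does not, though not all of them gave high counts. Whether that contrast carries the high counts was not tested.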

How the results depend on the processing

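Counts of distinct sets of values, fits without arrays numbered 1, without sex-linked genes or with a spread per cell type, and list tests under other scalings or left-out arrays were chosen after seeing the data. Of 2705 values of named genes under other settings, 2544 kept direction and side of the threshold, 132 no longer passed it, 29 newly passed it and none changed direction. Where not stated, the cause was not tested.

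With 1 fit of all 18 arrays, which shares 1 spread between cell types of unequal spread, the counts were 632 in ES cells, 210 in fibroblasts and 0 in brain. In ES cells the count of 2 became 1 with the mean of a gene's probe sets, 5 without dim genes, 4 with array weights and 6 without both arrays numbered 1, and 0 to 6 without single arrays. In fibroblasts the count of 2058 became 30 at 2-fold, by construction, and 900 to 2609 without single arrays. In brain the count of 1 became 2 over all probe sets, 0 without sex-linked genes, by construction, and 1 to 2 without single arrays. Ccnc in ES cells was -1.76 with the mean of its probe sets (adjusted p = 0.0733, range over all settings 4.17e-07 to 0.299) and -2.25 without both arrays numbered 1, and -2.56 to -2.24 without single arrays. In fibroblasts it was -1.31 to -1.27 and in brain -0.82 to -0.53 without single arrays; the second probe set gave -1.39 to -0.96 in ES cells, -0.81 to -0.70 in fibroblasts and -0.36 to -0.16 in brain. The overlap of ES cells and fibroblasts became 0 with the mean of probe sets.

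The mean effect of 51 genes became 291 with array weights, 89 with a spread per cell type and 402 without both ES cell arrays numbered 1, and 21 to 204 without single arrays. Fibroblasts against ES cells, 170 genes, became 53 and 553 in the last 2 settings and 30 to 391 without single arrays. Brain against ES cells, 47 genes, became 25 with quantile normalization, 26 with array weights, 3 and 474 in those 2 settings and 9 to 220 without single arrays. Fibroblasts against brain, 57 genes, became 1525 with array weights, 539 and 226 in those 2 settings and 6 to 115 without single arrays. The 23 list calls became 0 with an estimated correlation, 19 with quantile normalization (15 shared), 23 with median centring, 27 without both arrays numbered 1 (22 shared) and 21 to 25 without single arrays.

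With the replicate number as a block the counts were 1 in ES cells, 15 in brain, 414 for the mean effect, 523 for fibroblasts against ES cells, 323 for brain against ES cells and 183 for fibroblasts against brain. Ccnc kept its value with the block, -2.37 in ES cells (adjusted p = 0.0677) and -0.69 in brain (0.0426). In ES cells same-numbered arrays correlated at 0.37, 0.32 and 0.08. Knockout array 3 correlated best with wild-type array 2 (0.20), and every other ES cell array with its own number. The numbers were not taken to pair these arrays, although both arrays numbered 1 shared a higher signal of Eif2s3y and lower X-linked escape genes. The ES cell tests without the block thus leave differences shared by same-numbered arrays in the spread. The block made 25 list calls, 22 of them shared, and ended that of the interneuron list in ES cells (adjusted p = 0.0534), where the sex-linked list passed with it (0.0457). In fibroblasts and brain the block changed no other call of a list or of Ccnc, and no count by over 1.5 times, beyond those printed. Signal over background was not given on these arrays, and the 3 arrays per group limit the precision.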

Other observations

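Single members of 5 further lists passed the test in knockout fibroblasts, while camera called none of these lists in the deposited values. Of 10 endothelial markers 4 rose and 0 fell, also when adjusted over the list alone. They included the VEGF receptor gene Flt1 (log2 fold change 0.40, SE 0.09) and the claudin gene Cldn5 (0.36, SE 0.09). Camera gave the endothelial list an adjusted p = 0.0648, and 0.0447 with quantile normalization. With an estimated correlation, on the deposited values, its adjusted p was 0.667. Of 18 imprinted genes 3 rose and 2 fell (5 and 3 adjusted over the list alone), with Impact at 0.45 (SE 0.08), Peg3 at -0.33 (SE 0.07) and Mest at -0.38 (SE 0.09; camera adjusted p = 0.712). Of 22 targets of p53, 4 rose and 3 fell (5 and 3 adjusted over the list alone; 3 and 4 over all genes with quantile normalization), with Gadd45a (0.29, SE 0.05) and Eda2r (0.35, SE 0.08) up and Sesn1 (-0.30, SE 0.08) down (camera adjusted p = 0.438). Of 19 genes of hypoxia and glycolysis 3 rose, including Ndrg1 (0.52, SE 0.09), and 0 fell (3 and 1 adjusted over the list alone; 3 and 2 over all genes with quantile normalization; camera adjusted p = 0.907). Of 14 neural progenitor genes 3 rose, including the intermediate filament gene Nes (0.36, SE 0.06), and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.462). Impact, Gadd45a, Ndrg1 and Nes kept the call without each array in turn. Without single arrays the call was lost for Flt1 (every array but wild-type array 1, adjusted p up to 0.0855), Cldn5 (every array but wild-type array 3 and knockout array 3, 0.113), Mest (every array but knockout array 2, 0.105), Peg3 (wild-type arrays 2 and 3, 0.0662), Eda2r (wild-type arrays 1 and 3 and knockout array 2, 0.0685) and Sesn1 (wild-type arrays 1 and 2 and knockout arrays 1 and 2, 0.126).

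Of 10 measured genes within 6 places of Ccnc in the RefSeq order, looked at after the results were seen, 2 fell and 0 rose in knockout fibroblasts, and 0 passed in ES cells or brain by limma (2 in each with an unadjusted p below 0.05). Pnisr fell by 0.22 log2 units in fibroblasts (SE 0.06, limma adjusted p = 0.0492) and lost the call without any array other than knockout array 3 (adjusted p up to 0.179). Tstd3, the gene next to Ccnc, fell in fibroblasts (log2 fold change -0.86, SE 0.06, limma adjusted p = 8.67e-05) and kept the call without each array in turn. It stood at -0.35 in brain (SE 0.09, adjusted p = 0.627) and at 0.58 in ES cells (SE 0.19, adjusted p = 0.547). The effect was lower than in ES cells by 1.44 log2 units in fibroblasts (adjusted p of the difference 0.00164) and by 0.93 in brain (adjusted p = 0.0443).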
